A study of Mus musculus with 6 samples.

How the data were processed

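Expression was measured by RNA-seq of mRNA in 6 libraries, 3 from PBS control cultures and 3 from cultures given PM2.5 at 100 µg/ml. Per the labels' protocols, naive CD4 T cells were isolated from the spleen with a CD4 T cell kit, seeded on plates coated with anti-CD3 and anti-CD28 and grown in RPMI medium with 10% serum and 55 µM mercaptoethanol. The polarising mixture held anti-IFN-gamma and anti-IL-4 at 5 µg/ml each, IL-6 at 20 ng/ml, IL-23 at 10 ng/ml, TGF-beta at 2 ng/ml and IL-2 at 5 ng/ml. Total RNA was taken with TRIzol after 4 days and sequenced on an Illumina instrument.

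The table of genes that the authors deposited gives raw counts per Ensembl gene for each library, per the file headers, and the values are whole numbers with a different total in each library. It also gives FPKM values made by the authors, per the file headers. For the 9540 genes with more than 100 counts, these FPKM equal the count divided by the library's total of counts and by 1 fixed length per gene to within 0.00083%, so they carry no further normalisation. TopHat2 2.0.6 and the mm10 genome are named in the submitters' processing notes. The program that counted the reads, its annotation, its treatment of reads that fall in more than 1 gene or place and the strand setting are not given in the sources used here. Counts of overlapping, antisense and near-identical genes can therefore share reads and are uncertain. The table holds 34745 genes with symbols and coordinates. Of these, 34344 are found in GENCODE M21, all on the same chromosome and 29300 with the same start, so the coordinates are those of the table, in mm10. There are 59 symbols held by more than 1 gene ID, and 27 symbols turned into dates, so genes were followed by ID.

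Library totals were 22154837, 19511561 and 22353131 counts in the control and 27215853, 26121365 and 25397965 counts in the PM2.5 group. The 10 most abundant genes held 6.16 to 6.74% of the counts of a library. TMM factors were 1.02, 1.02 and 1.03 against 0.978 in each PM2.5 library, so the composition of the libraries differed between the groups. Replicates of a group were compared with a chi-square over the genes with at least 20 counts in the pair, scaled to the pair's totals. It was 7.57 to 9.89 per degree of freedom for each pair, above counting error for the sum over genes. A few genes whose counts jump between libraries can carry this sum. It therefore does not show that most genes vary by more than counting error, or that the replicates are separate cultures. Each library was kept as 1 replicate.

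The choice of test, samples, gene lists and named genes was made before the data were examined. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12967 genes with 99.9% of the counts and left out 21778. They were tested in edgeR 4.0.16 under R 4.3.3 with TMM scaling, glmQLFit with robust estimation and a two-sided quasi-likelihood F test of PM2.5 against PBS control over all 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The common biological coefficient of variation was 8.17%. SEs are the absolute log2 fold change over the square root of F. Levels are means with SDs of TMM-scaled CPM, n = 3; sums of markers are scaled by library totals. Where a group had 0 counts, the fold is a bound against 3 counts over the group. Medians of lists include no gene with 0 counts in a group.

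The named genes are the 12 largest rises and 12 largest falls among genes that passed, reached a mean of 5 CPM in at least 1 group and had groups that did not overlap, without predicted models, receptor segments, pseudogenes and small RNAs. To these were added up to 4 members of each list with the smallest adjusted p, and Got1, Hif1a, Foxp3, Il17a, Il17f, Ahr and Cyp1a1 in any case, 133 genes together. Some of the genes that the rule names are not reported here. A gene named outside this rule is marked as chosen after its values were seen, or belongs to a list and is named only for a call that an alternative ended or a sign that one turned.

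The 30 fixed lists cover Th17, Treg, Th1, Th2, co-inhibitory receptor, and naive and central memory genes; aryl hydrocarbon receptor, NRF2, HIF-1, p53 and NF-kB target genes; glycolysis, glutamine and malate-aspartate shuttle, and cholesterol synthesis genes; ATF4 and amino acid response, unfolded protein response, heat shock, metal response, proliferation, interferon response and DNA methylation genes; mitochondrially encoded genes; and markers of B cells, macrophages and monocytes, neutrophils, dendritic cells, NK cells, CD8 and gamma-delta T cells, erythroid cells, and stromal and endothelial cells. One listed gene had no match in the table. Lists with at least 3 genes tested, 26 of the 30, were tested against all other genes with camera of limma 3.58.1 on log2 CPM (prior count 2, correlation between genes 0.01), adjusted over the lists. Of these, 6 passed, 4 up and 2 down, and 2, the ATF4 and the cholesterol synthesis genes, passed with the correlation estimated from the data. Fry asks whether the members of a list move one way on balance and sets no list against other genes; 25 lists passed it. A further 6 lists, cytosolic and mitochondrial aminoacyl-tRNA synthetases, interferon-inducible GTPases, fatty acid synthesis genes, STAT5 target genes and immediate early genes of T cell receptor signalling, were chosen after seeing the data and adjusted among themselves.

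The gene test was tested on simulated data drawn from the means and totals of these libraries with 200 of 12967 genes changed. For the comparison of PM2.5 with PBS control it recovered 44% of the 50 genes changed 1.25-fold, 74% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, and called 11 of 12767 unchanged genes. In the real comparison 70.6% of the genes passed, far more than the simulated share, so these rates need not hold for it.

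Each result was computed again with DESeq2 1.42.0, limma-voom, relative log expression factors, library totals alone, no filter on low counts, a filter at a mean of 5 CPM, the replicate number as a block, limma with a trend on log2(FPKM + 1) for genes with a mean FPKM of at least 1 in a group, and without each library in turn. Lists were also tested with fry, with an estimated correlation, with the block, with both filters and without each library. Chosen after seeing the data were thinning of every library to the smallest total, offsets from a smooth of each library's deviations on GC content and length (from the transcripts of GENCODE M21, known for 99.6% of the genes tested), and leaving out 322 genes of unstable counts, those with a coefficient of variation above 30% within a group at a mean of at least 50 counts. Also chosen then, the members of the ATF4 and cholesterol synthesis lists were each set against the 200 genes outside the list nearest in mean control count. Reads were not used here, so isoforms, strand and duplicates were not analysed.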

Results

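RNA was sequenced from mouse T helper cells grown with or without fine particulate matter. Naive CD4 T cells from the spleens of female C57BL/6 mice aged 6 weeks were stimulated through CD3 and CD28 for 4 days in the presence of IL-6, IL-23, TGF-beta and IL-2 together with antibodies against IFN-gamma and IL-4, conditions that drive differentiation into IL-17 producing (Th17) cells. At 6 h of stimulation the cultures received either a suspension of PM2.5, airborne particles of under 2.5 micrometres, at 100 µg/ml or PBS alone. Each group holds 3 libraries, 6 in all. The libraries of the PBS control held 22154837, 19511561 and 22353131 counts and those of the PM2.5 group 27215853, 26121365 and 25397965, so every PM2.5 library was deeper than every control library. A count of 0 allows a level of up to 0.110 to 0.154 CPM (counts scaled to a common library total) in a single library, a floor set at 3 counts that covers counting error only. The sources used here do not say whether the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

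The comparison asks how exposure to PM2.5 alters the transcripts of CD4 T cells under Th17 polarisation, with attention to the balance of Th17 and regulatory T cell genes, to the glutamate-handling enzyme Got1 and to the hypoxia factor Hif1a. The clearest change was a rise of the genes of the amino acid stress response. All 19 genes of the ATF4 list rose in the PM2.5 group, by a median of 7.72-fold, among them the stress transcription factor Atf4 (5.54-fold), Ddit3 (16.0-fold), which encodes the stress factor CHOP, and the glutathione-degrading enzyme Chac1 (98.3-fold). All 20 cholesterol synthesis genes fell, by a median of 2.06-fold. The T cell growth factor Il2 rose from 1.92 ± 0.23 to 308 ± 26.7 CPM (SD, n = 3), 161-fold. Th17 and Treg genes moved both ways: Foxp3, the master regulator of regulatory T cells, fell 1.95-fold and Il17a 1.10-fold, the receptor gene Ahr fell 5.07-fold and the costimulatory receptor gene Tnfrsf4 rose 6.23-fold.

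In total 9149 of 12967 genes tested (70.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4567 higher and 4582 lower in the PM2.5 group. Of these, 2446 changed at least 2-fold, 844 higher and 1602 lower. The median size of change among the genes that passed was 0.59 on the log2 scale. The values of the 2 groups did not overlap for 9707 genes (74.9%), against 10% by chance with 3 libraries against 3, and 9036 genes met both criteria. Libraries correlated at 0.993 to 0.994 within groups and at 0.941 between groups over log2 CPM of the genes tested, and the first principal component, which separated the groups, held 86.8% of the variance. The count of genes changed at least 2-fold was 1307 among the 9919 genes with a mean of at least 5 CPM, and 995 with limma on log2(FPKM + 1), in which low values are drawn together.

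**Figure D1:**
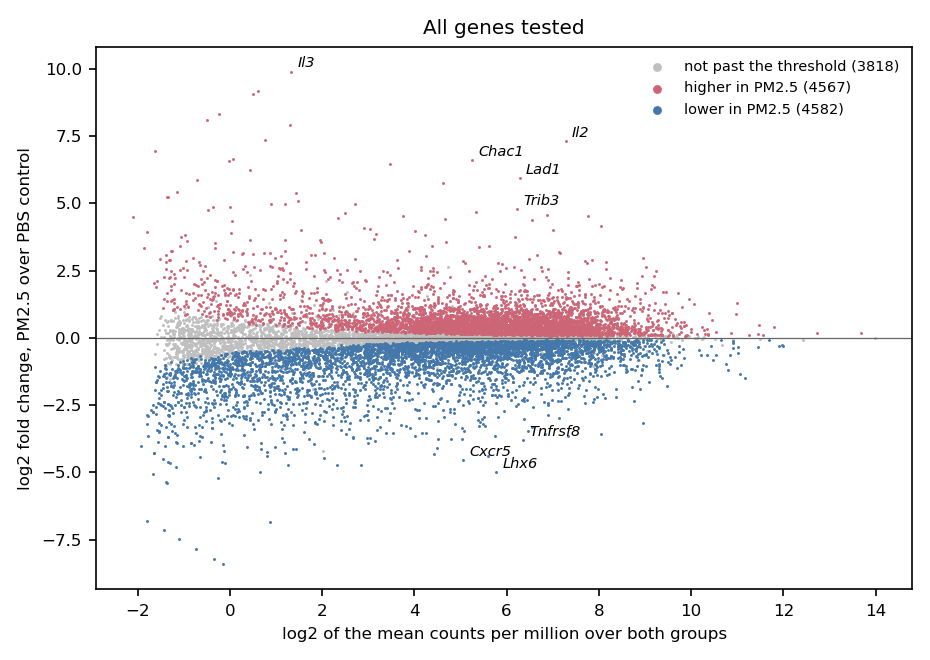
Each point is 1 of the 12967 genes tested, with the log2 of its mean CPM over both groups on the x axis and the log2 fold change of PM2.5 over PBS control on the y axis (n = 3 libraries per group). Red points are the 4567 genes that rose and blue points the 4582 that fell; the fold change drawn for 12 genes with no count in one of the groups, Il3 among them, depends on the prior count.

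The 12 largest rises included the genes of 2 cytokines. Il3, the gene of the haematopoietic growth factor interleukin-3 (ENSMUSG00000018914, mm10 chromosome 11, 54265303 to 54267277), had 0 counts in the control libraries and 387 over the PM2.5 libraries, 5.03 ± 0.88 CPM, at least 110-fold higher against a floor of 3 counts over the control group. Il2 (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959) had a log2 fold change of 7.33 (SE 0.11, adjusted p = 6.76e-10); all cultures had received IL-2 protein. Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381) rose from 0.757 ± 0.137 to 75.5 ± 2.26 CPM, a log2 fold change of 6.62 (SE 0.09, adjusted p = 6.70e-12). The others of the 12 largest rises lay between log2 fold changes of 4.65 and 6.46. They were Aldh1l2, a mitochondrial enzyme of folate metabolism, the anchoring filament protein gene Lad1 (2.47 to 153 CPM), the cysteine-producing enzyme Cth, the cystine transporter Slc7a11, the T cell receptor-associated adaptor Trat1, the prostaglandin synthase Ptgs2, the pseudokinase Trib3, the alanine aminotransferase Gpt2 and Kdelr3, a receptor that returns proteins to the endoplasmic reticulum. Slc7a11 and Trib3 are members of the ATF4 list, as is Chac1.

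The largest fall was that of Lhx6, a homeodomain transcription factor gene (ENSMUSG00000026890, chromosome 2, 36081953 to 36105408), from 107 ± 12.1 to 3.33 ± 0.65 CPM, a log2 fold change of -5.00 (SE 0.16, adjusted p = 6.48e-07). Cxcr5, the chemokine receptor that guides cells to B cell follicles (ENSMUSG00000047880, chromosome 9, 44511788 to 44556391), fell from 63.7 ± 1.89 to 2.70 ± 0.27 CPM (-4.56, SE 0.08, adjusted p = 1.49e-11). The remainder of the 12 largest falls ranged from -4.72 to -3.79. They were Pigz, which adds a mannose to membrane anchors, Fam101b, Sertad4, the interferon-inducible GTPase Tgtp1, the glycosyltransferase B3gnt8, the glutamate decarboxylase Gad2, the phosphate transporter Slc34a3, Apol7e, the acid-sensing channel Asic1 and Tnfrsf8, which encodes the activation receptor CD30 (13.8-fold lower). Tgtp1 has a near-identical neighbour, Tgtp2, with which it can share reads, so its own value is uncertain. On log2(FPKM + 1) many of these rises and falls were over 1.5 times smaller, with Aldh1l2 at 1.521 and Sertad4 at -1.059.

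**Figure D2:**
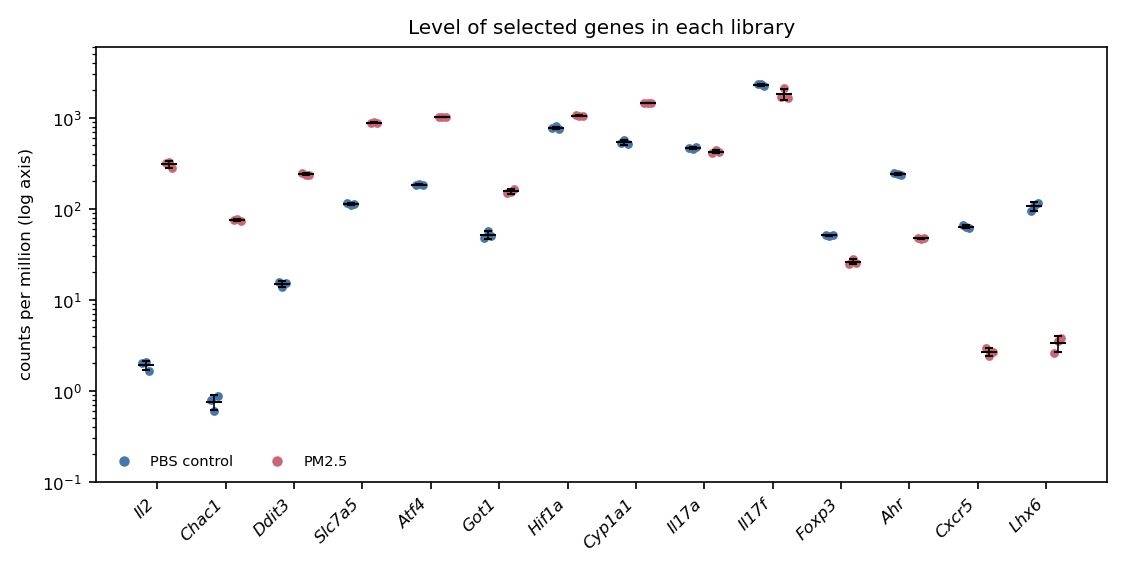
CPM of 14 genes on a log axis, with 1 point per library (blue, PBS control; red, PM2.5), and the mean and SD of each group in black (n = 3). Il2 stood at 1.92 and 308 CPM in the control and PM2.5 groups, whereas the groups lay close together for Il17a (464 and 423).

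Among the 16 Th17 genes, 4 rose, 10 fell and 2 did not pass. The ligand-activated receptor gene Ahr (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038) fell from 240 ± 4.27 to 47.4 ± 0.83 CPM (-2.34, SE 0.03, adjusted p = 7.30e-12), and Maf, a transcription factor of Th17 and follicular helper cells, fell by 1.63 on the log2 scale. The chemokine Ccl20 (1.94) and the transcription factor Irf4 (1.31) rose. The signature cytokine Il17a fell from 464 ± 10.6 to 423 ± 17.4 CPM (-0.13, SE 0.04, adjusted p = 0.00660) and its relative Il17f from 2323 ± 58.4 to 1813 ± 256 CPM (-0.36, SE 0.11, adjusted p = 0.0357). Chosen after the values were seen, Csf2, the gene of GM-CSF, rose by 4.53, Il21 rose by 0.91 and Stat3, which relays the IL-6 signal, fell by 1.03 on the log2 scale. As a list the Th17 genes did not stand apart from the other genes tested (median -0.21, camera adjusted p = 0.303).

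Il17a kept its call in 16 of 17 alternatives. It stood at -0.004 with offsets for GC content and gene length, chosen after seeing the data (adjusted p = 0.928, over a range of 0.000671 to 0.928), but these offsets also moved the median of all genes by 0.10. Il17f lost its call without any single one of the control libraries, without PM2.5 replicate 1 or without PM2.5 replicate 3 (adjusted p = 0.0953, 0.113, 0.084, 0.1 and 0.08), with no filter on low counts (0.0727) and with those offsets (0.106), over a range of 7.57e-07 to 0.113.

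Of the 17 regulatory T cell (Treg) genes, 5 rose, 8 fell and 4 did not pass, with a median of -0.39 (camera adjusted p = 0.434); fry, which asks whether the members move one way on balance, pointed the other way (adjusted p = 0.334). Foxp3 (ENSMUSG00000039521, chromosome X, 7579676 to 7595243) fell from 51.2 ± 0.86 to 26.2 ± 1.77 CPM (-0.97, SE 0.06, adjusted p = 1.34e-07). Nt5e, which encodes the adenosine-producing enzyme CD73 (-1.38), and Il2ra, the IL-2 receptor alpha chain (-0.64), also fell, whereas the costimulatory receptor Tnfrsf4 (2.64) and the inhibitory receptor Ctla4 (1.69) rose.

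The genes of other helper lineages moved both ways. Of the 14 Th1 genes, 6 rose and 6 fell, with a median of 0.17 (camera adjusted p = 0.952). The median turned to -0.67 with the filter at 5 CPM and -0.30 with limma on FPKM, which tested only 9 and 12 of the 14 genes. The chemokines Ccl4 (2.78) and Ccl3 (2.49) and the interferon gene Ifng (1.69) rose, and the granule protease Gzmb fell (-1.42). Of the 8 Th2 genes tested of 12, 4 rose and 3 fell, with a median of 0.37 but a mean of -0.05. The median turned to -0.76 and -0.29 under the same alternatives, which tested only 5 and 6 of the 8 genes. The chemokine receptor Ccr8 (-2.70), Il4ra (-0.69) and the cytokine Il9 (-1.28) fell and the receptor Ccr4 (1.27) rose. Camera gave the Th2 list an adjusted p of 0.952 and upward, fry one of 0.00384 and downward. All 10 co-inhibitory receptor genes changed, 6 up and 4 down (median 0.66, camera adjusted p = 0.310): Cd200 (4.15) and Btla (2.88) rose with Ctla4, and Pdcd1, the gene of PD-1, fell (-0.75). Of the 10 naive and central memory genes 6 fell and 1 rose (median -0.65, camera adjusted p = 0.0701), with falls of the transcription factor Tcf7 (-1.18), the IL-7 receptor Il7r (-1.03) and the egress receptor S1pr1 (-0.95).

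The amino acid response stood out among the 26 lists tested by camera. Its 19 genes had log2 fold changes of 1.53 to 6.62 (median 2.95, camera adjusted p = 1.93e-10, and adjusted p = 0.0445 with an estimated correlation). Atf4 (ENSMUSG00000042406, chromosome 15, 80255184 to 80257540) rose from 185 ± 3.94 to 1023 ± 3.23 CPM, Slc7a5, a transporter of large neutral amino acids, from 113 ± 2.00 to 888 ± 6.21 CPM, and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, from 9.35 ± 0.56 to 224 ± 3.02 CPM. All 14 genes of the unfolded protein response rose (median 0.77, 1.71-fold, camera adjusted p = 1.13e-05), but the list did not pass with its correlation estimated (adjusted p = 0.153 with an estimated correlation). Herpud1, which acts in the clearance of misfolded proteins (2.84), and the chaperones Dnajb9 (1.78) and Hspa5 (1.69) rose more than the transcription factor Xbp1 (0.99). Dnajc3, the smallest rise at 0.13, lost its call with library totals, the filter at 5 CPM and limma on FPKM (0.064, 0.062 and 0.062, with adjusted p = 0.0878, 0.0863 and 0.0652). These 3 alternatives moved all genes by a median of -0.064, -0.066 and -0.063 on the log2 scale, so calls of changes this small depend on the scaling. Of 10 heat shock genes tested 9 rose and none fell (median 0.52, camera adjusted p = 0.0116, and adjusted p = 0.153 with an estimated correlation), among them Hspd1 (0.81), Hspe1 (0.71), Hspa1b (1.49) and the co-chaperone Chordc1 (0.43). Hspa8, at 0.09, lost its call under the same 3 alternatives (0.026, 0.024 and 0.026; adjusted p = 0.413, 0.426 and 0.437) and without PM2.5 replicate 2 (0.057). The cytosolic chaperone Hspa1b has a near-identical copy, Hspa1a, and Hspd1 and Hspe1 have pseudogenes, so these values are uncertain.

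**Figure D3:**
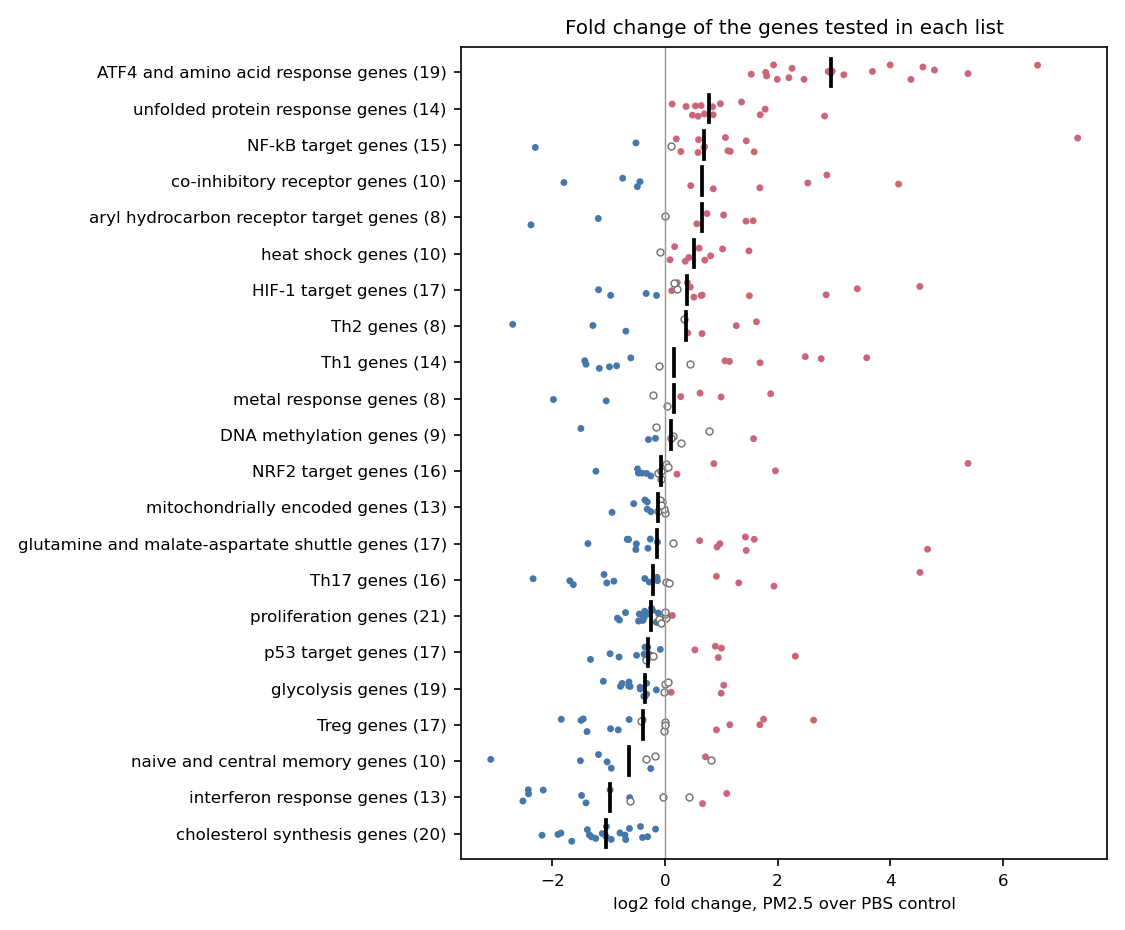
Each point is a gene tested, grouped by list (the number tested in brackets), with its log2 fold change of PM2.5 over PBS control on the x axis; red points rose, blue points fell, open points did not pass an adjusted p of 0.05, and black bars are list medians. Over the lists shown, which leave out the markers of other cell types, the medians run from -1.04 for the cholesterol synthesis genes to 2.95 for the ATF4 and amino acid response genes.

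The 20 cholesterol synthesis genes moved the other way (median -1.04, camera adjusted p = 1.65e-07, and adjusted p = 0.0445 with an estimated correlation). The demethylase Cyp51 fell from 256 ± 8.45 to 81.2 ± 2.09 CPM, and Insig1, a sterol-sensing partner of the pathway, fell by 1.23 on the log2 scale. In the same libraries the summed NK cell markers went from 25.7 to 10.1 CPM and the CD8 and gamma-delta T cell markers from 49.0 to 25.6 CPM. The smallest fall, that of Msmo1 (-0.17), lost its call with DESeq2 (adjusted p = 0.102) and without control replicate 2 or 3 or PM2.5 replicate 1 or 3 (0.0729, 0.0551, 0.0645 and 0.107).

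Got1, the cytosolic aspartate aminotransferase (ENSMUSG00000025190, chromosome 19, 43499752 to 43524605), rose 3.00-fold, from 52.0 ± 4.82 to 156 ± 9.80 CPM (log2 fold change 1.59, SE 0.07, adjusted p = 4.30e-07). The glutamine and malate-aspartate shuttle list it belongs to held 7 genes that rose and 9 that fell, with a median of -0.13, a mean of 0.40 and a camera adjusted p of 0.952 and upward. Glutamate dehydrogenase Glud1 (1.44), the glutamine transporter Slc1a5 (1.43) and Gpt2 (4.66) rose. Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530) rose from 776 ± 26.9 to 1060 ± 15.7 CPM (0.45, SE 0.03, adjusted p = 3.58e-07). Of the 17 HIF-1 target genes tested of 18, 11 rose, Hif1a itself among them, and 4 fell (median 0.40, camera adjusted p = 0.0935). Ndrg1, a stress-response gene (4.53), the angiogenic factor Vegfa (3.42) and Ddit4 (0.66), a regulator of mTOR signalling, rose, and the oxygen-sensing hydroxylase Egln3 fell (-1.18). Glycolysis genes mostly fell, 13 of 19, with 3 that rose (median -0.36, camera adjusted p = 0.0765). The list passed with the filter at 5 CPM (0.0346) and without control replicate 2 (0.0405), over a range of 0.0346 to 0.485 in the alternatives that use camera. Lactate dehydrogenase Ldha (-0.64) and enolase Eno1 (-0.44), which have pseudogenes and so uncertain values, fell (Eno1 was at -0.212 with the GC and length offsets), and hexokinase Hk2 (1.05) and phosphofructokinase Pfkp (2.00-fold) rose.

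Genes of xenobiotic and oxidant sensing were split. Of 8 aryl hydrocarbon receptor target genes tested of 10, 5 rose and 2 fell (median 0.66, camera adjusted p = 0.141). The list passed with the filter at 5 CPM (adjusted p = 0.0254, over a range of 0.0254 to 0.485 in those alternatives). That filter kept 4 of the 8 genes, all risers. Cyp1a1, the cytochrome most used as a readout of this receptor (ENSMUSG00000032315, chromosome 9, 57697613 to 57703822), rose from 536 ± 28.2 to 1455 ± 16.3 CPM (1.44, SE 0.04, adjusted p = 2.46e-10), with Tiparp (1.04), Ahrr (0.75) and Cyp1b1 (0.57), while Ahr itself fell. Of 16 NRF2 target genes tested of 17, 4 rose and 6 fell. The haem-degrading enzyme Hmox1 (1.96), Slc7a11 (5.38) and the exporter Abcc1 (0.87) rose and the peroxidase Prdx1 fell (-0.49). The NRF2 list had a median of -0.08, 0.04 with the GC and length offsets, a mean of 0.32, a camera adjusted p of 0.716 and downward, and a fry adjusted p of 0.00346 and upward. Of 8 metal response genes tested of 11, 4 rose and 2 fell (median 0.16, camera adjusted p = 0.682 and upward, fry adjusted p = 0.000182 and downward). The zinc exporter Slc30a1 (1.88) and the metallothionein Mt2 (2.00-fold) rose, and the zinc importer Slc39a10 (-1.98) and the ferritin gene Fth1 (-1.04), which has pseudogenes, fell.

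NF-kB target genes rose in 12 of 15 cases and fell in 2 (median 0.69, camera adjusted p = 0.00439, and adjusted p = 0.147 with an estimated correlation). Besides Il2, the subunit genes Rel (1.44), Nfkb1 (1.16) and Nfkb2 (1.07) rose, and the coactivator Bcl3 fell (-2.30). Of 21 proliferation genes 15 fell and 1 rose (median -0.24, camera adjusted p = 0.00521, and adjusted p = 0.147 with an estimated correlation); the ribonucleotide reductase subunit Rrm2 (-0.84), the helicase subunit Mcm6 (-0.81), Ccnb2 (-0.70) and the topoisomerase Top2a (-0.45) fell. Of 17 p53 target genes 5 rose and 10 fell (median -0.31, camera adjusted p = 0.310), with rises of Plk2 (2.32) and the cell cycle inhibitor Cdkn1a (0.90) and falls of Btg2 (-0.97) and the death effector Pmaip1 (-0.81). Of 13 interferon response genes tested of 19, 8 fell and 2 rose (median -0.97, camera adjusted p = 0.0695), and 9 fell when adjusted over the list alone. With no filter on low counts, where all 19 were tested, the list passed (adjusted p = 0.0208, over a range of 0.0208 to 0.279 with camera). The transcription factor Irf7 (-2.43), Oasl2 (-2.16), the RNA sensor Ddx58 (-1.48) and Stat2 (-0.97) were among those that fell. No other fixed list gave a different count adjusted over the list alone. Of 9 DNA methylation genes 1 rose and 3 fell, with a median of 0.12 that was -0.02 without genes of unstable counts (camera adjusted p = 0.952): Gadd45b rose (1.57), and Tet1 (-1.49) and the methylation maintenance genes Uhrf1 (-0.29) and Dnmt1 (-0.17) fell, Uhrf1 standing at -0.138 and Dnmt1 at 0.06 with the GC and length offsets (Dnmt1 adjusted p = 0.0665; range over its alternatives 3.16e-05 to 0.0665).

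Mitochondrially encoded transcripts took 4.76, 5.14 and 4.82% of the counts in the control libraries and 4.18, 4.22 and 4.30% in the PM2.5 libraries. Of the 13 genes 7 fell and none rose (median -0.12, camera adjusted p = 0.0695), including mt-Nd5 (-0.55), mt-Nd1 (-0.35), mt-Cytb (-0.32) and mt-Co3 (-0.31). The list passed with the filter at 5 CPM (adjusted p = 0.0312) and without control replicate 1 (0.0352), over a range of 0.0312 to 0.668 with camera. With the GC and length offsets 6 fell, 3 rose and the median was 0.01, with mt-Nd1 at -0.232, mt-Cytb at -0.201 and mt-Co3 at -0.171.

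Markers of other cells that a spleen could contribute were low, and they moved both ways. The summed CD8 and gamma-delta T cell markers went from 49.0 ± 1.02 to 25.6 ± 1.24 CPM; of 4 tested 3 fell, among them the T cell receptor delta constant gene Trdc (-0.97), the gamma segment Trgv2 (-2.73) and Cd8a (-0.86), and Cd8b1 rose (0.55; list median -0.91, camera adjusted p = 0.237). The 3 NK cell markers tested of 8, the cytotoxic genes Prf1 (-1.34) and Gzma (-1.29) and the receptor Klri2 (-1.21), all fell (median -1.29, camera adjusted p = 0.0695), and the sum went from 25.7 ± 1.29 to 10.1 ± 0.52 CPM. The stromal and endothelial sum went from 86.1 ± 2.77 to 49.1 ± 1.77 CPM, most of it from Pecam1, an adhesion molecule gene that T cells also express (-0.75); the collagen genes Col1a2 (-2.12) and Col1a1 (-1.22) fell from under 1 CPM (3 of 8 tested, median -1.22, camera adjusted p = 0.141). The macrophage and monocyte sum went from 7.82 ± 1.54 to 5.38 ± 0.53 CPM; of 3 genes tested of 12, Mrc1 (-3.97) and Cd68 (-0.77) fell and the Fc receptor Fcgr3 rose (1.06; median -0.77, camera adjusted p = 0.515). B cell markers went from 5.38 ± 0.57 to 21.4 ± 0.51 CPM, most of it from the transcription factor gene Ebf1, which rose (2.61 on the log2 scale, 6.09-fold), while Cd79b fell (-2.59) and the other 8 markers were below the filter. Ms4a1, an abundant B cell transcript, had 0 counts in every library. Dendritic cell markers went from 1.07 ± 0.19 to 2.90 ± 0.52 CPM; of 2 tested of 7, Zbtb46 rose (2.54) and Itgax fell (-1.17). The 1 neutrophil marker tested of 8, Ly6g, fell from 5.66 to 0.61 CPM (-3.14), and the 7 erythroid markers were all below the filter, with 0.05 CPM in the control and 0 counts in the PM2.5 group. The neutrophil markers S100a8 and S100a9, the macrophage marker Lyz2 and the erythroid markers Hbb-bs and Hba-a1 had 0 counts in every library. Ly6g and Cd68 alone therefore do not show RNA of neutrophils or macrophages. The calls of Fcgr3, Itgax and Col1a1, each at about 2 CPM or less, were lost without some single libraries, Fcgr3 without control replicate 1 or PM2.5 replicate 1 or 2 (adjusted p = 0.0605, 0.106 and 0.0925), Itgax without control replicate 3 (0.0561), and Col1a1 without any library except PM2.5 replicate 3 (0.0853 to 0.0992). Itgax (0.14) and Col1a1 (0.138) also lost theirs with DESeq2, and Col1a1 with the GC and length offsets (0.11). Over all alternatives the adjusted p ranged from 0.00576 to 0.106 for Fcgr3, 0.00787 to 0.14 for Itgax and 0.00817 to 0.138 for Col1a1. Col1a1 moved to -0.736 without PM2.5 replicate 1 and -1.897 without PM2.5 replicate 3, and Fcgr3 to 0.673 without control replicate 3.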

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

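The thinned counts, the GC and length offsets and the fit without genes of unstable counts were chosen only after the results were seen. Over all alternatives the number of genes past the threshold stayed within 7337 and 9582, against 9149. Without each library in turn it was 8777 to 8998; between 527 and 630 of the 9149 genes lost their call and 0 changed sign. The count of genes changed at least 2-fold fell from 2446 to 1307 with the filter at 5 CPM, where 9919 genes were tested and 1229 of the 2446 were kept, and to 995 with limma on log2(FPKM + 1), of which 975 were among the 2446; the added 1 draws low values together and 10600 genes were tested. Without each library it was 2507 to 2579. Library totals made 44.4% of the calls rises and the GC and length offsets 56.5%, against 49.9%; these offsets moved the median of all genes by 0.10 on the log2 scale.

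Of 26 lists, 6 passed camera, 2 with an estimated correlation and 25 with fry, which sets no list against other genes; without each library 6 to 7 passed, with no filter 7 and with the filter at 5 CPM 9. Fry gave the opposite sign to camera for the Th2 (adjusted p = 0.00384), NRF2 (0.00346) and metal response (0.000182) lists, none of which passed camera, and the cause was not tested.

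The GC and length offsets turned the sign of 19 of 344 genes named or listed, 9 of them past the threshold in either fit: to 0.055 for Dnmt1, 0.144 for Bst2, 0.15 for Mcm7, 0.151 for mt-Atp8, 0.082 for mt-Co1, 0.013 for mt-Nd2, 0.231 for mt-Nd4l, 0.267 for Pfkl and 0.149 for Tkt. Beyond the shift of 0.10 the cause was not tested. Of the 344 genes, 278 kept sign and side of the threshold in each alternative that tested them, 23 lost a call in some alternative and 26 gained one; of the 133 named genes 127 kept both.

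With the replicate block 9002 genes passed, 8844 of them among the 9149, 2435 changed at least 2-fold, and 6 lists passed; Col1a1 was at an adjusted p of 0.0556 with the block. The deviations of libraries with the same number correlated at 0.013, 0.007 and 0.045, and those of other pairs at -0.037 to 0.023, so the numbers give little sign of pairing. PBS control 2 and PBS control 3 correlated best with the PM2.5 library of the same number, and PBS control 1 with PM2.5 2 (0.023). Settings for tables that hold only normalised values, a pseudocount of 0.1, a fit without a trend and quantile normalisation, were not run, since counts were tested. Depth limits genes near the floor of 0.110 to 0.154 CPM per library.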

Other observations

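The 6 lists below and the tests on thinned counts, on GC and length offsets, on genes of like level, on RNA from other cell types and on genes of unstable counts were chosen only after the results were seen. The enzymes that charge cytosolic tRNAs rose almost together: 18 of 20 rose and none fell (median log2 fold change 1.16, camera adjusted p = 2.12e-08, and adjusted p = 0.0636 with an estimated correlation), with Cars at 2.79, Nars at 2.29 and Iars at 2.02, the synthetases for cysteine, asparagine and isoleucine. The 17 mitochondrial synthetases split into 6 that rose, 4 that fell and 7 that did not pass (median 0.14, camera adjusted p = 0.602); adjusted over the list alone 5 rose. The interferon-inducible GTPases, which act against intracellular pathogens, all fell, 14 of 14 tested of 15 (median -1.92, 3.79-fold lower, camera adjusted p = 4.47e-07, and adjusted p = 0.0447 with an estimated correlation), among them Gbp2 from 725 ± 12.9 to 142 ± 2.92 CPM and Irgm1 (-2.77). Tgtp1 fell by 4.41 and can share reads with its near-identical neighbour Tgtp2.

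Of 12 fatty acid synthesis genes tested of 13, 3 rose and 6 fell (median -0.27, camera adjusted p = 0.230), with falls of the elongase Elovl6 (-2.13) and the desaturase Fads2 (-1.40). Of 14 immediate early genes of T cell receptor signalling 9 rose and 3 fell, or 4 adjusted over the list alone (median 0.56, mean 0.12, camera adjusted p = 0.230 and upward, fry adjusted p = 0.0106 and downward): Dusp5 (1.36) and Ier3 (1.30) rose, while Egr3 fell from 42.5 ± 1.82 to 3.16 ± 0.05 CPM and Egr1 fell by 1.65. Of 8 STAT5 target genes 4 rose and 3 fell (median 0.03, -0.04 with library totals and with the filter at 5 CPM and -0.03 with limma on FPKM; mean -0.05; camera adjusted p = 0.602), with Ccnd2 (1.30) and Bcl2 (1.29) up and the feedback inhibitors Socs1 (-2.34) and Socs2 (-1.18) down.

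These lists were used to test hypotheses. If the synthetases follow the ATF4 genes, the cytosolic list should exceed the mitochondrial one by at least 0.5; the medians differed by 1.025. The lists were picked after such genes had been seen to rise, so this difference describes the rise and leaves its source open. Whether the STAT5 targets rose with Il2 was not settled, since their median of 0.026 lies under the 0.5 asked for by less than the members' spread (median absolute deviation 1.58). The immediate early genes did not fall together with Egr3: 9 of 14 rose, and their median of 0.56 lay above the -0.5 asked for by slightly more than their spread (0.979). A fall of Egr3 with a smaller set such as Egr1 and Nr4a1, which also fell, stays open.

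For the rise of the ATF4 genes, the PM2.5 libraries were deeper; with all thinned to 19511561 counts the median was 2.929, but thinning moved genes by a median of 0.0147, less than their SE, so it says little on depth. Depth acts on a gene through its count, yet the members exceeded the 200 genes nearest in control count by a median of 2.902 (median absolute deviation 1.57), which argues against it. With the GC and length offsets the median was 2.981 (1.669 to 6.749). Markers of B, myeloid, neutrophil, dendritic and erythroid cells together rose by 10.2 CPM, from 20.0 to 30.3, while Atf4 alone rose from 185 to 1023 CPM. A response of the T cells to PM2.5 remains a candidate explanation, which these data cannot separate from a difference in the cultures that goes with the group, such as medium use or cell density.

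The fall of the cholesterol synthesis genes had a median of -1.012 with thinned counts, which again says little on depth. Against genes of like control count the members had a median of -1.137 (median absolute deviation 0.508), which argues against depth as the whole cause. With the GC and length offsets all 20 stayed below 0, with a median of -0.998 (0.538), which argues against those trends. Markers of NK, CD8 and gamma-delta T, neutrophil, macrophage and stromal cells were lower by 83.6 CPM together, from 174 to 90.7 CPM. The list was lower by 1136 CPM, from 2446 to 1310 CPM. A loss of RNA from other cells could give the whole fall only if they held much of the list's RNA in the control. Their markers were low there, but summed markers do not measure how much of the list's RNA came from other cells. The marker lists were also chosen because they fell. The stromal sum was mostly Pecam1, which T cells also express, at 84.3 CPM in the control and 48.1 CPM in the PM2.5 group. The comparison therefore cannot decide, and a loss of RNA from other cells stays open. A response to PM2.5 also stays open, as does a difference in the cultures that goes with the group.

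In 322 genes (2.48% of those tested) counts jumped between libraries of 1 group, although libraries of a group correlated at 0.993 to 0.994. Chosen after the values were seen, Actb had 2723, 4633 and 2795 CPM in the control and 1709, 915 and 1001 CPM in the PM2.5 libraries. Of these genes 36.3% overlapped another counted gene against 22.3% of 10868 others (odds ratio 1.99, 95% interval 1.56 to 2.52, Fisher's exact p = 2.21e-08), so reads assigned to one or the other neighbour may explain part, with the interval too wide to place the ratio above or below 2. The other 63.7% overlapped no gene with a mean of at least 10 counts, and 46.3% no gene of the table at any count; moved reads do not reach these 46.3% by the positions given in the table. Genes with a pseudogene named after them were 1.54 times as frequent by odds (0.751 to 2.84, Fisher's exact p = 0.18), which leaves shared reads open. Pseudogenes under other names were not counted.

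The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 9149 genes and the highest of the other 9 gave 0 in edgeR and in limma-voom (41 to 70 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. Each of the other 9 splits mixes both groups on each side, so the difference between the groups widens the spread within a side. Few calls could then be made, and the 0 does not show what would be called without a difference. For genes changed at least 2-fold the values were 2446 and 0, again 1 of 10. For lists past camera the real split gave 6 and the others 3 to 6, so 2 of 10 gave as many. With a correlation of 0.01 camera thus passed lists in splits where no gene passed. These splits also keep part of the group difference between their sides, which can make lists pass. They therefore cannot show whether the adjusted p-values of camera are too small, and that stays open. The unfolded protein response, heat shock, NF-kB and proliferation lists did not pass with an estimated correlation, so their calls rest on the fixed setting. The estimate was 0.132 for the unfolded protein response. For the heat shock, NF-kB and proliferation lists it was -0.091, -0.019 and -0.028, so a correlation above 0.01 did not cost these their call.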
